A study of Mus musculus with 15 samples.

How the data were processed

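Gene expression was measured by paired-end RNA sequencing in 15 libraries from mouse Abelson pre-B lines, which are B-cell progenitors transformed by the v-Abl kinase. Every culture had been kept for 48 h in imatinib, an inhibitor of that kinase. The labels give 5 groups of 3 libraries each. Rag_SPIC_noDOX and Rag_SPIC_DOX are Rag-deficient cells with a tetracycline-inducible SPIC construct, without and with doxycycline, and Rag_SPIC_DOX_shBCLAF1 adds a short hairpin RNA against BCLAF1. Art and Art_shBCLAF1 are Artemis-deficient cells without and with that hairpin. No label names a control hairpin. RNA was taken up with RNeasy columns and made into libraries with TruSeq reagents. Whether the 3 libraries of a group are separate cultures is not given in the sources used here, so the p-values measure only the spread between these samples.

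The authors' processing notes name the mouse genome build mm9, Subread, featureCounts 1.4.5, edgeR and limma, without a role or an order for each, and the versions of the others are not given in the sources used here. The authors deposited 4 tables, each holding log2 values of all 15 libraries with the authors' log2 fold changes. The p-values (p_value) in these tables were made by the authors with limma before deposit, raw and adjusted. The expression values are log2 CPM (read counts scaled by an effective library size), with 0.5 added to each read count. They are the same in every table that lists a gene (largest difference 0), and 100% of the values below 1000 reads return to whole numbers within 0.05 reads. Each table lists only protein-coding genes that passed the authors' own adjusted p of 0.05, the highest being 0.0499. One column name for Art replicate 3 differs by 1 character from its label and was matched on that basis. In all, 152 duplicate rows were merged, and 4 symbols belong to more than 1 gene identifier.

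The tests were run over the 11551 genes found in any of the 4 tables. The plan had named each comparison's own table, but those genes had been chosen by the comparison under test, so the union was used after the files had been seen. An estimated 11728 genes were tested by the authors, and about 177 of them are in none of the tables. Counts of genes that did not pass are therefore counts within the union.

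The genes named for each comparison include the 8 highest and 8 lowest log2 fold changes among changed genes of above-median expression whose groups did not overlap. For each comparison, limma 3.58.1 in R 4.3.3 was fitted to the 6 libraries of its 2 groups with a mean-variance trend in the prior. Benjamini-Hochberg adjustment was over all 11551 genes, and a gene was taken as changed at an adjusted p below 0.05. A fold change is the difference of mean log2 CPM between the groups, given with its standard error, and a positive value means higher in the group named before the word against. All tests were two-sided. The effect of the hairpin label was compared between Art and Rag_SPIC_DOX cells with an interaction term over 12 libraries.

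Gene lists were tested with camera in limma at its preset correlation of 0.01, and again with the correlation estimated from the libraries, each with adjustment over 84 tests. The 21 lists were ETS-family factors, pre-B-cell receptor signalling, PU.1 and SPIB targets, heme and iron genes, the RAG-break program, NF-kB targets, p53 targets, the interferon response, the cell cycle, the light-chain stage of pre-B cells, endoplasmic reticulum and integrated stress, apoptosis regulators, splicing genes, cholesterol synthesis, glycolysis with hypoxia, myeloid markers, T-cell and NK markers, erythroid and megakaryocyte markers, plasma-cell markers, replication histones, and immediate-early and stress genes. Together they hold 396 genes, written down from general knowledge. For each list the genes that passed were counted with adjustment over all genes and also with adjustment over the list alone. Genes shared by the hairpin effects were counted beside the number to be found if the calls were independent. Pairs of comparisons with a group in common are not independent, so their covariance across genes was set beside that of 50 simulations without change.

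To measure how much such a fit can find, changes of 1 or 2 log2 units were seeded in 100 genes of values simulated from each pair of groups. Recovery of the smaller change was 41% for Art against Rag_SPIC_noDOX, 67% for Rag_SPIC_DOX against Rag_SPIC_noDOX, 71% for Rag_SPIC_DOX_shBCLAF1 against Rag_SPIC_DOX and 39% for Art_shBCLAF1 against Art. The larger change was recovered in 66%, 88%, 91% and 86% of the genes, with 6, 11, 10 and 3 false calls among 11551 genes. A seeded gene list was found in all 4 comparisons, with 0, 1, 1 and 2 other lists called. Its camera adjusted p was 2.24e-51, 5.94e-85, 1.27e-82 and 1.07e-41, whereas the smallest of any list in the data was 2.12e-14. The seeded list was thus too strong to be missed. Finding it cannot show how camera does with weaker lists or with genes that move together.

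The groups, comparisons, tests, gene lists, rule for naming genes and most alternatives were fixed before the data were examined. Chosen after the results were seen were the union of the tables, the lists described in detail, the fits on each table alone and with voom, the list counts without single libraries, and the grouping of the patterns weighed at the end. A few genes that the naming rule picked are not reported here.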

Results

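RNA was measured in 15 libraries of mouse Abelson pre-B cells under imatinib, in 5 groups of 3. The effective library sizes were 17.8, 18.1 and 17.8 M reads in Rag_SPIC_noDOX, 23.2, 22.1 and 21.6 M in Rag_SPIC_DOX, and 22.7, 25.9 and 27.1 M in Rag_SPIC_DOX_shBCLAF1. They were 25.9, 17.2 and 5.81 M in Art and 23.0, 18.7 and 18.3 M in Art_shBCLAF1. Of 11551 genes, 145 had 0 reads in Art replicate 3, against 19 to 56 in the other libraries. The root-mean-square log2 difference of Art replicate 3 from Art replicates 1 and 2 was 0.94 and 0.95, that of Rag_SPIC_DOX replicates 1 and 2 was 0.83, and other pairs within a group lay between 0.24 and 0.58. The first principal component held 58.5% of the variance, and the 3 Rag_SPIC_DOX libraries were spread along it at 5.80, -41.7 and -15.0.

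The genes the labels name were measured in every library, as log2 CPM. Bclaf1 (ENSMUSG00000037608), the gene the hairpin is directed at, was at a mean of 7.70 ± 0.07 (SD, n = 3) in Rag_SPIC_noDOX, 7.73 ± 0.04 in Rag_SPIC_DOX and 8.04 ± 0.06 in Rag_SPIC_DOX_shBCLAF1. It was at 7.32 ± 0.79 in Art, with 7.81, 7.75 and 6.41 in replicates 1 to 3, and at 8.32 ± 0.03 in Art_shBCLAF1. Its mRNA was thus higher, not lower, in the libraries labelled shBCLAF1, and every direction given for them is that of the label. Spic (ENSMUSG00000004359), an ETS-family transcription factor and the gene carried by the inducible construct, was at 0.82 ± 0.62 in Rag_SPIC_noDOX, 4.21 ± 0.44 in Rag_SPIC_DOX and 7.46 ± 0.04 in Rag_SPIC_DOX_shBCLAF1. In Art cells, whose label names no SPIC construct, Spic had 46, 21 and 6 reads, and in Art_shBCLAF1 511, 378 and 509. Myc, which encodes a growth-promoting transcription factor, was at 5.60 ± 0.18, 6.21 ± 2.21 and 9.21 ± 0.08 in the Rag groups in that order, and at 4.07 ± 0.20 in Art and 8.79 ± 0.11 in Art_shBCLAF1.

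**Figure D1:**
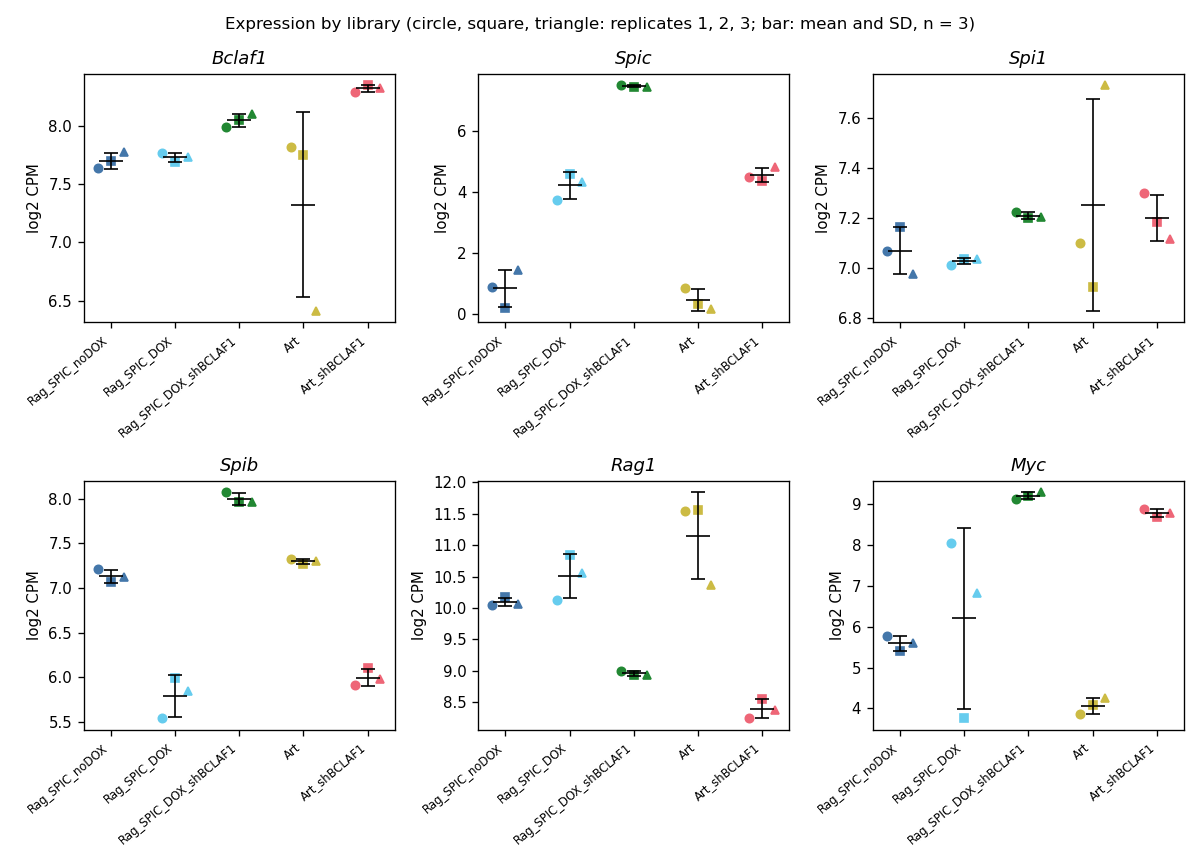
Log2 CPM of Bclaf1, Spic, Spi1, Spib, Rag1 and Myc in each library of the 5 groups, with circles, squares and triangles for replicates 1 to 3 and bars for the mean and SD (n = 3). Bclaf1 is at 8.04 and 8.32 in the libraries labelled shBCLAF1, and at 7.70, 7.73 and 7.32 in the others.

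By their labels, Art cells can cut DNA with the RAG recombinase but cannot open the hairpin ends for repair, whereas Rag cells cannot make these breaks. The mRNA levels do not show these deficiencies. Rag1 was at 10.09 and Rag2 at 6.0 log2 CPM in Rag_SPIC_noDOX, and Dclre1c, the Artemis gene, was at 5.12, 4.99 and 2.87 in Art replicates 1 to 3 against a mean of 4.68 in Rag_SPIC_noDOX. Art against Rag_SPIC_noDOX therefore addresses what unrepaired RAG breaks do to expression, although the 2 lines differ in more than this genotype. In limma, 594 genes changed, of which 298 were higher in Art and 296 lower, and 314 changed by at least 1 log2 unit. The values of the 2 groups did not overlap for 37.9% of all genes, where 10% would be so if no gene differed. Carmil2 (ENSMUSG00000050357), a regulator of actin, rose 3.27-fold (log2 fold change 1.71, SE 0.11, n = 3 per group, adjusted p = 0.00983). Other large rises were Mid1 (1.59, SE 0.24), Itgam (1.57, SE 0.15), Arpp21 (1.53, SE 0.25), Dpp7 (1.49, SE 0.27), Hip1r (1.46, SE 0.18), Ret (1.46, SE 0.10) and Id3 (1.44, SE 0.24). Itgam encodes an integrin chain of myeloid cells and Id3 an inhibitor of E-protein transcription factors. Arrdc3 (ENSMUSG00000074794), an alpha-arrestin, fell by 1.87 log2 units (SE 0.17, adjusted p = 0.0104). Gadd45a (-1.44, SE 0.24), Tacc3 (-1.31, SE 0.26), Spats2 (-1.30, SE 0.20), Ube2c (-1.26, SE 0.22), Cdca3 (-1.23, SE 0.09), Ticrr (-1.17, SE 0.20) and Txnip (-1.15, SE 0.10) also fell. Tacc3, Ube2c and Cdca3 act in mitosis, and Ticrr in the start of DNA replication.

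Cell-cycle genes were lower in Art. Of 40 measured, 11 fell and 29 did not pass, and 27 fell when adjusted over the list alone. Their median log2 fold change was -0.79 (camera adjusted p = 2.12e-14, and adjusted p = 0.116 with an estimated correlation). Examples are Myc (-1.53, SE 0.16), the cyclins Ccnd2 (-1.32) and Ccna2 (-0.97), and Birc5 (-1.10), a mitotic gene. Among 12 replication histones, whose near-identical paralogs make their values uncertain, 3 fell (8 adjusted over the list alone), with a median of -1.03 (camera adjusted p = 1.91e-05, and adjusted p = 0.205 with an estimated correlation). Hist1h1b fell by 2.49, Hist1h1d by 1.22 and Hist1h1c by 0.77. Of 31 p53 targets, 3 fell (9 adjusted over the list alone), namely Plk3 (-1.55), Gtse1 (-0.73) and Mdm2 (-0.60). The list's median was -0.31 (camera adjusted p = 0.00164, and adjusted p = 0.436 with an estimated correlation). Pre-B-cell receptor genes had a median of 0.17, and of 33 measured 2 rose, among them Plcg2 (0.80), the same 2 adjusted over the list alone (camera adjusted p = 0.00887, and adjusted p = 0.436 with an estimated correlation). Without Art replicate 3, 39 cell-cycle genes, 10 histones and 19 p53 targets fell, 3 p53 targets rose, and 13 pre-B-cell receptor genes rose and 2 fell.

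The genes of the RAG-break program had a median of 0.34 in Art (camera adjusted p = 0.164), with 1 of 17 higher and 2 lower, and 3 higher and 2 lower when adjusted over the list alone. NF-kB targets had a median of 0.31 (camera adjusted p = 0.0644). Ebi3 (1.77) and Cd40 (1.59) rose, and Tnf (-1.44) and Map3k8 (-0.81) fell, while 23 of 27 did not pass. Without Art replicate 3, 10 genes of the RAG-break program rose and 3 fell, and 14 NF-kB targets rose and 6 fell. Rag1 had a log2 fold change of 1.06 (SE 0.33, adjusted p = 0.137). The authors' deposited table gives it as 1.46 (limma adjusted p = 3.08e-08). Bclaf1 was at -0.38 (adjusted p = 0.586), Spic at -0.38 (0.58), Spi1 at 0.18, Spib at 0.17, Rag2 at 0.29, Dclre1c at -0.36, Syk at 0.04 and Blnk at -0.27, none of which passed. Without Art replicate 3, Rag1 was at 1.46 (limma adjusted p = 2.47e-11), Rag2 at 0.75 (limma adjusted p = 2.57e-07) Dclre1c at 0.37 (limma adjusted p = 0.000843), Spib at 0.17 (limma adjusted p = 0.0294) and Blnk at -0.21 (limma adjusted p = 0.0135). The authors' deposited table, in which that library has little weight, gives 0.71 for Rag2 (limma adjusted p = 0.000101), 0.36 for Dclre1c (limma adjusted p = 0.00116) and -0.19 for Blnk (limma adjusted p = 0.0414). Among markers of other cells, Csf1r (-1.68), Tyrobp (-1.38) and Fcgr3 (-1.06) fell, and Lck (1.35), Tcf7 (0.64) and Jchain (2.04) rose. Across genes, which are not independent replicates, the log2 fold change had a Spearman correlation of 0.37 with GC content, and the deviation of Art replicate 3 from its group had one of 0.62. Without Art replicate 3 the count rose to 5473. It was 1 without Rag_SPIC_noDOX replicate 2, and 0 in limma without Rag_SPIC_noDOX replicate 1 or 3 or Art replicate 1 or 2, with 1636, 1493, 2303 and 2232 genes at an unadjusted p below 0.05.

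Rag_SPIC_DOX against Rag_SPIC_noDOX addresses what SPIC does to pre-B cells without RAG breaks, since doxycycline switches on the construct. Doxycycline itself is in the same comparison. The size of the change ran against the Spic level across the Rag_SPIC_DOX libraries. Replicate 2, with the most Spic (4.59 log2 CPM), lay nearest to Rag_SPIC_noDOX, at root-mean-square log2 differences of 0.46 to 0.54. Replicate 1, with the least (3.72), lay farthest, at 0.78 to 0.81. The changes below therefore cannot be assigned to the Spic level. In limma, 1367 genes changed, 365 higher and 1002 lower, and 319 changed by at least 1 log2 unit, of which 20 were higher. The share that was higher, 26.7%, depends on the libraries and the fit, being 50.5% without Rag_SPIC_DOX replicate 2 and 48.8% with array weights. It was lower in other fits, such as 16.8% with libraries centred on their medians and 3.33% with the replicate number as a block. The groups did not overlap for 40.7% of genes, where 10% would be so if no gene differed. Spic rose 10.4-fold (log2 fold change 3.38, SE 0.35, n = 3 per group, adjusted p = 0.00607), from between 20 and 47 reads per library to between 305 and 531. Spib, a related ETS factor of B cells, fell 2.53-fold (-1.34, SE 0.12, adjusted p = 0.00395). Srebf2 (1.04, SE 0.11), the transcription factor that drives sterol synthesis, rose. Lrpprc (0.76, SE 0.18), Tmem109 (0.70, SE 0.16), Marcks (0.66, SE 0.11), Acly (0.66, SE 0.13), Ppme1 (0.66, SE 0.15) and Ipo7 (0.65, SE 0.17) followed. Arrdc3 fell by 1.92 log2 units (SE 0.08, adjusted p = 0.000389). The interferon-induced GTPase gene Gbp4 (-1.79, SE 0.10), Dpysl3 (-1.70, SE 0.23), Micall2 (-1.65, SE 0.19), Scn8a (-1.63, SE 0.18), Rapgef3 (-1.51, SE 0.12), Epha2 (-1.45, SE 0.15) and Cpt1a (-1.36, SE 0.17) fell as well. Cpt1a carries fatty acids into mitochondria.

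Cholesterol synthesis was the list called as higher with all libraries in. Of 18 genes, 10 rose (13 adjusted over the list alone), with a median of 1.0 (camera adjusted p = 5.12e-08, and adjusted p = 0.455 with an estimated correlation). The enzyme genes Cyp51 (1.64) and Msmo1 (1.56) were among them. All 12 replication histones had values below 0 and 8 fell (12 adjusted over the list alone), among them Hist1h1b (-2.21), Hist1h2bc (-1.93) and Hist1h1d (-1.73), with uncertain values owing to paralogs (camera adjusted p = 7.54e-07, and adjusted p = 0.349 with an estimated correlation). Of 31 p53 targets 9 fell (15 adjusted over the list alone), with Pmaip1 (-1.24), Eda2r (-1.18), Mdm2 (-0.87) and Cd80 (-0.77) the largest and a median of -0.25 (camera adjusted p = 2.32e-06, and adjusted p = 0.451 with an estimated correlation). Immediate-early and stress genes had 7 of 22 lower and 1 higher (12 and 2 adjusted over the list alone) and a median of -0.46 (camera adjusted p = 0.00198, and adjusted p = 0.451 with an estimated correlation). Fos (-2.37), Dusp1 (-1.97) and Hspa1b (-0.79) were among the falls. Without Rag_SPIC_DOX replicate 3, 2 cholesterol genes rose, and 2 histones, 2 p53 targets and 1 immediate-early gene fell, with 11, 8, 15 and 14 at an unadjusted p below 0.05 and medians of 0.98, -1.32, -0.29 and -0.46. Without replicate 2, 17 cholesterol genes rose and 16 p53 targets fell, and immediate-early genes had 12 lower and 5 higher, while cell-cycle genes had 17 higher and 3 lower (camera unadjusted p = 0.000707) and glycolysis and hypoxia genes 11 higher and 3 lower (camera unadjusted p = 0.000237).

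Interferon genes were lower too, with Zbp1 (-0.99), Isg15 (-0.88), Dhx58 (-0.71) and Gbp3 (-0.60) among the 6 of 25 that fell (7 adjusted over the list alone), at a median of -0.18 (camera adjusted p = 0.0328, and adjusted p = 0.451 with an estimated correlation). Splicing genes had 5 of 24 lower, with a median of -0.19 (camera adjusted p = 0.00417, and adjusted p = 0.522 with an estimated correlation), and 7 lower and 1 higher adjusted over the list alone. They include the kinases of splicing factors Clk1 (-0.76) and Clk4 (-0.55), and Tra2a (-0.50) and Srsf3 (-0.35). Without Rag_SPIC_DOX replicate 3, limma called 0 interferon and 0 splicing genes, with 7 and 8 at an unadjusted p below 0.05, and without replicate 1 or 2 it called 9 or 8 splicing genes lower and 5 or 9 interferon genes lower. In the pre-B-cell receptor list, whose median was -0.01, 4 of 33 fell and 1 rose, the same adjusted over the list alone, against 10 and 6 without Rag_SPIC_DOX replicate 2 (median -0.13) and 1 lower without replicate 3. Zap70 (-1.30), Blk (-0.79) and Cd72 (-0.53) fell. Fcrla (-1.10), Fcgr2b (-0.83) and Bcl6 (-0.63) fell among PU.1 and SPIB targets, and the iron exporter gene Slc40a1 (-2.00) and Blvrb (-0.48) among heme and iron genes, whose median was 0.07. Hmox1, which encodes a heme-degrading enzyme, was at a log2 fold change of 1.72 (SE 0.82, adjusted p = 0.181), which did not pass. Its values in Rag_SPIC_DOX replicates 1 to 3 were 4.11, 0.41 and 2.86 log2 CPM, against a mean of 0.74 in Rag_SPIC_noDOX. The authors' deposited table gives 2.02 for Hmox1 (limma adjusted p = 1.57e-06). In that table Rag_SPIC_DOX replicate 3 holds 94.6% of its group mean, so the authors' values for this comparison rest mostly on that library for the doxycycline side. Bclaf1 was at 0.03 (SE 0.07, adjusted p = 0.799), Spi1 at -0.04, Rag1 at 0.42 (0.147), Rag2 at 0.46 (0.082), Dclre1c at -0.28, Syk at -0.01 and Blnk at -0.24, and none of them passed. In the authors' deposited table Rag1 is at 0.48 (limma adjusted p = 0.00294), Rag2 at 0.53 (0.00038), Dclre1c at -0.46 (2.65e-05) and Blnk at -0.17 (0.0302). Without Rag_SPIC_DOX replicate 2 the count was 4569, without Rag_SPIC_noDOX replicates 1, 2 and 3 it was 12, 401 and 15, and without Rag_SPIC_DOX replicate 3 it was 58. Myc was at 8.06, 3.76 and 6.83 in Rag_SPIC_DOX replicates 1 to 3, a spread wider than the difference of the group means.

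Rag_SPIC_DOX_shBCLAF1 against Rag_SPIC_DOX addresses what BCLAF1 knockdown, by label, does where SPIC is on without RAG breaks. In limma, 6186 genes changed, 3290 higher and 2896 lower, and 1654 changed by at least 1 log2 unit. The groups did not overlap for 66.1% of genes, where 10% would be so if no gene differed. Bclaf1 rose 1.25-fold (log2 fold change 0.32, SE 0.06, n = 3 per group, adjusted p = 0.00537), against its label. In the authors' deposited table, where Rag_SPIC_DOX replicate 3 holds 94.6% of its group mean, Bclaf1 is at 0.32 (limma adjusted p = 1.2e-07). Spic rose by a further 9.51-fold (3.25, SE 0.21, adjusted p = 0.00022). The level of SPIC mRNA was therefore not held constant. Its effect cannot be told apart from that of the label in this comparison. Nefh (3.56, SE 0.79), Myc (3.0, SE 1.0, adjusted p = 0.0419), Tubb3 (2.89, SE 0.45), Blk (2.68, SE 0.10), Enpep (2.58, SE 0.08) and Bcat1 (2.40, SE 0.75) rose. Without Rag_SPIC_DOX replicate 2, Myc was at 1.77 and Bcat1 at 1.49, and without replicate 3 neither passed (3.30 and 2.58, limma adjusted p = 0.0826 and 0.0762). Nefh and Tubb3 encode neuronal cytoskeleton proteins, Blk a Src-family kinase of B cells and Bcat1 an enzyme of branched-chain amino acids. Dtx4 (-2.79, SE 0.16), Itgb3 (-2.51, SE 0.18), Itgam (-2.50, SE 0.18), Ankrd33b (-2.47, SE 0.16), Zfp704 (-2.39, SE 0.24), Plscr4 (-2.31, SE 0.15), Ralgps2 (-2.26, SE 0.14) and Phka1 (-2.25, SE 0.20) fell. Spib rose 4.60-fold (2.20, SE 0.12, adjusted p = 0.000149), and Spi1 (0.18) and Dclre1c (0.45) rose less. The recombinase genes Rag1 (-1.55, SE 0.17) and Rag2 (-1.26, SE 0.14) and the kinase gene Syk (-0.66, SE 0.15) fell, and Blnk was at -0.21 (adjusted p = 0.208).

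NF-kB targets were lower in these libraries labelled shBCLAF1. Of 27, 16 fell and 1 rose, the same adjusted over the list alone, with Ebi3 (-4.24, SE 0.22), Ltb (-2.19) and Traf1 (-1.88) among them and a median of -0.46 (camera adjusted p = 0.000105, and adjusted p = 0.278 with an estimated correlation). In the RAG-break program 11 of 17 fell and 1 rose, again the same adjusted over the list alone, including Ccl3 (-4.18, SE 1.03), Cd44 (-2.68) and Gadd45a (-1.49). Its median was -0.63 (camera adjusted p = 0.00387, and adjusted p = 0.284 with an estimated correlation). By their label these cells make no RAG breaks, so the fall of this list is not the loss of a response to them. Myeloid markers had 9 of 11 lower and 1 higher, also adjusted over the list alone, with Csf1r at -3.37 and Lyz2 at -2.65 and a median of -2.24 (camera adjusted p = 0.000699, and adjusted p = 0.278 with an estimated correlation).

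Splicing genes were higher, with 17 of 24 up and 1 down (18 and 1 adjusted over the list alone) and a median of 0.32 (camera adjusted p = 0.000148, and adjusted p = 0.451 with an estimated correlation). Srsf6 (1.38), Srsf7 (1.18), Tra2a (0.94) and U2af1 (0.93) rose most. Of 18 cholesterol genes 13 rose (14 adjusted over the list alone), among them Idi1 (2.01) and Cyp51 (1.38), with a median of 0.93 (camera adjusted p = 0.000311, and adjusted p = 0.609 with an estimated correlation). Immediate-early and stress genes had 15 of 22 higher (17 adjusted over the list alone), with Fosb (4.91, SE 0.16), Fos (4.14), Egr1 (2.03) and Hspa8 (1.70) and a median of 0.63 (camera adjusted p = 0.000311, and adjusted p = 0.436 with an estimated correlation). The stress genes of the endoplasmic reticulum and amino-acid response had a median of 0.50, with 9 of 21 higher and 2 lower, the same adjusted over the list alone (camera adjusted p = 0.0396, and adjusted p = 0.609 with an estimated correlation). Asns (1.51), Psat1 (1.49) and Atf3 (1.49) rose. PU.1 and SPIB targets went in both directions, 11 of 31 higher and 7 lower (12 and 7 adjusted over the list alone), such as Fcrla (3.21) and Tlr9 (1.37) up and Cybb (-1.47) down (median 0.01, camera adjusted p = 0.729). Pre-B-cell receptor genes had 8 of 33 higher and 5 lower (7 and 5 adjusted over the list alone), with Pik3cd (1.21), Vpreb2 (1.13) and Plcg2 (0.95) up and Syk (-0.66) down (median 0.07, which centring on library medians turned to -0.03, camera adjusted p = 0.699). Without Rag_SPIC_DOX replicate 1 there were 11 higher and 9 lower, and without replicate 3 there were 6 and 2. The light-chain list had 5 of 28 higher and 13 lower, the same adjusted over the list alone, with Cd2 (2.08) up and Il7r (-1.21) down (median -0.21, camera adjusted p = 0.0543), and 3 and 12 without Rag_SPIC_DOX replicate 3. Cell-cycle genes had 9 of 40 higher and 14 lower, the same adjusted over the list alone (median 0.10, camera adjusted p = 0.589), but 19 and 14 without Rag_SPIC_DOX replicate 1 and 4 and 12 without replicate 3. Without Rag_SPIC_DOX_shBCLAF1 replicate 2 or 3 the count was 3945 or 4078. Centring each library on its median moved the median log2 fold change of all genes from 0.05 to -0.05, and 45.0% instead of 53.2% of the genes that changed were then higher.

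Art_shBCLAF1 against Art addresses what BCLAF1 knockdown, by label, does in cells with unrepaired RAG breaks. In limma, 5664 genes changed, 2884 higher and 2780 lower, and 3409 changed by at least 1 log2 unit. The groups did not overlap for 65.6% of genes, where 10% would be so if no gene differed. Bclaf1 was at a log2 fold change of 0.99 (SE 0.37, n = 3 per group), which did not pass (adjusted p = 0.0679). In the authors' deposited table it is at 0.55 (limma adjusted p = 8.31e-10), so both values go against the label. Spic rose 17.1-fold (4.1, SE 0.24, adjusted p = 0.000135), so here too its level changed together with the label. Bcat1 (5.06, SE 0.14, adjusted p = 3.52e-05), Pole2 (4.76, SE 0.25), Myc (4.72, SE 0.14), Psat1 (4.56, SE 0.13), Ccnd2 (4.55, SE 0.12), Mthfd1l (4.17, SE 0.16), Mthfd2 (3.71, SE 0.16) and Slc7a5 (3.63, SE 0.17) rose, the 8 highest log2 fold changes among changed genes of above-median expression whose groups did not overlap. Pole2 is a subunit of a replicative DNA polymerase, Psat1 acts in serine synthesis, Mthfd1l and Mthfd2 in mitochondrial folate metabolism, and Slc7a5 imports amino acids. Cacna1e (-5.68, SE 0.45), Mid1 (-5.27, SE 0.25), Itgam (-5.01, SE 0.26), Adamts7 (-3.99, SE 0.30), Tmtc1 (-3.97, SE 0.32), Ltb (-3.59, SE 0.39), Cdkn2a (-3.42, SE 0.54) and Shisa5 (-3.24, SE 0.27) fell, the 8 lowest by the same rule. Rag1 fell 6.76-fold (-2.76, SE 0.34, adjusted p = 0.00121), Spib 2.46-fold (-1.30, SE 0.11, adjusted p = 0.000319), and Blnk (-0.73, SE 0.15) and Syk (-0.61, SE 0.11) less. Spi1 was at -0.05, Rag2 at -0.65 (adjusted p = 0.206) and Dclre1c at -0.25, none of which passed. Without Art replicate 3, Rag2 was at -1.11 (limma adjusted p = 8.88e-08), Dclre1c at -0.98 (limma adjusted p = 2.27e-05), Spi1 at 0.19 (limma adjusted p = 0.0379) and Bclaf1 at 0.54 (limma adjusted p = 6.2e-06). The authors' deposited table gives -1.11 for Rag2 (limma adjusted p = 1.66e-07), -0.98 for Dclre1c (limma adjusted p = 1.36e-09) and 0.15 for Spi1 (limma adjusted p = 0.0221).

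Cell-cycle genes rose in 34 of 40 cases (36 adjusted over the list alone), at a median of 1.57 (camera adjusted p = 2.28e-11, and adjusted p = 0.346 with an estimated correlation). Besides Myc and Ccnd2, Cdc6 (2.90) and Ccne1 (2.69) were among them. Of 18 cholesterol genes 17 rose, as they did adjusted over the list alone, with Idi1 (3.98) and Sqle (3.24) among them and a median of 1.92 (camera adjusted p = 1.29e-07, and adjusted p = 0.137 with an estimated correlation). Glycolysis and hypoxia genes had 20 of 24 higher and 1 lower (21 and 1 adjusted over the list alone), with Ldha (3.39) and Hk2 (3.28) and a median of 1.97 (camera adjusted p = 2.32e-06, and adjusted p = 0.451 with an estimated correlation). Eno1 (3.27) and Gapdh (3.13) also rose, with values that processed pseudogenes make uncertain. Of the 21 genes of endoplasmic reticulum and integrated stress 15 rose and 1 fell (15 and 2 adjusted over the list alone), among them Psat1 (4.56), Asns (3.53), Nupr1 (3.52) and Chac1 (3.49), with a median of 1.10 (camera adjusted p = 0.000321, and adjusted p = 0.436 with an estimated correlation).

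NF-kB targets fell in 18 of 27 cases and rose in 2 (19 and 3 adjusted over the list alone), with Ebi3 (-6.01) and Cd40 (-3.80) down, Lta (6.63) up and a median of -1.34 (camera adjusted p = 5.54e-05, and adjusted p = 0.436 with an estimated correlation). In the RAG-break program 12 of 17 fell and 4 rose, the same adjusted over the list alone, with Il2ra (-2.82) and Cd80 (-2.39) among the falls and a median of -1.42 (camera adjusted p = 0.024, and adjusted p = 0.366 with an estimated correlation). Since this list also fell in Rag_SPIC_DOX cells, which make no RAG breaks by label, its fall here cannot be assigned to a lost break response. Of 31 p53 targets 16 fell and 3 rose, also adjusted over the list alone, such as Fas (-2.20) down and Plk3 (3.61) up (25 lower and 3 higher without Art replicate 3, median -0.66, camera adjusted p = 0.00321, and adjusted p = 0.455 with an estimated correlation). Interferon genes had 14 of 25 lower and 1 higher, the same adjusted over the list alone, with Irf7 (-2.42), Ifit3 (-2.16) and Oas3 (-1.86) and a median of -0.95 (camera adjusted p = 0.000636, and adjusted p = 0.266 with an estimated correlation). Light-chain-stage genes had 15 of 28 lower and 3 higher, also adjusted over the list alone, including Bcl6 (-2.84) down and Cd2 (3.79) up (median -0.73, camera adjusted p = 0.00224, and adjusted p = 0.455 with an estimated correlation). Of 33 pre-B-cell receptor genes 14 fell and 6 rose, the same adjusted over the list alone, with Vav3 (-2.04), Vpreb1 (-1.64) and Cd79b (-1.49) down and Ptpn6 (2.22) up (median -0.21, camera adjusted p = 0.189). Of the myeloid markers Lyz2 (-1.51) fell and Fcgr3 (1.27) rose, and of the T-cell markers Lck (-3.86) and Cd247 (-3.13) fell and Cd5 (3.30) rose. Without Art replicate 3 the count was 9252, and without Art_shBCLAF1 replicate 1 it was 3740. Across genes, which are not independent replicates, the log2 fold change had a Spearman correlation of -0.26 with GC content. Centring on the library medians moved the median log2 fold change of all genes from 0.05 to -0.18, and 37.5% instead of 50.9% of the genes that changed were then higher.

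**Figure D2:**
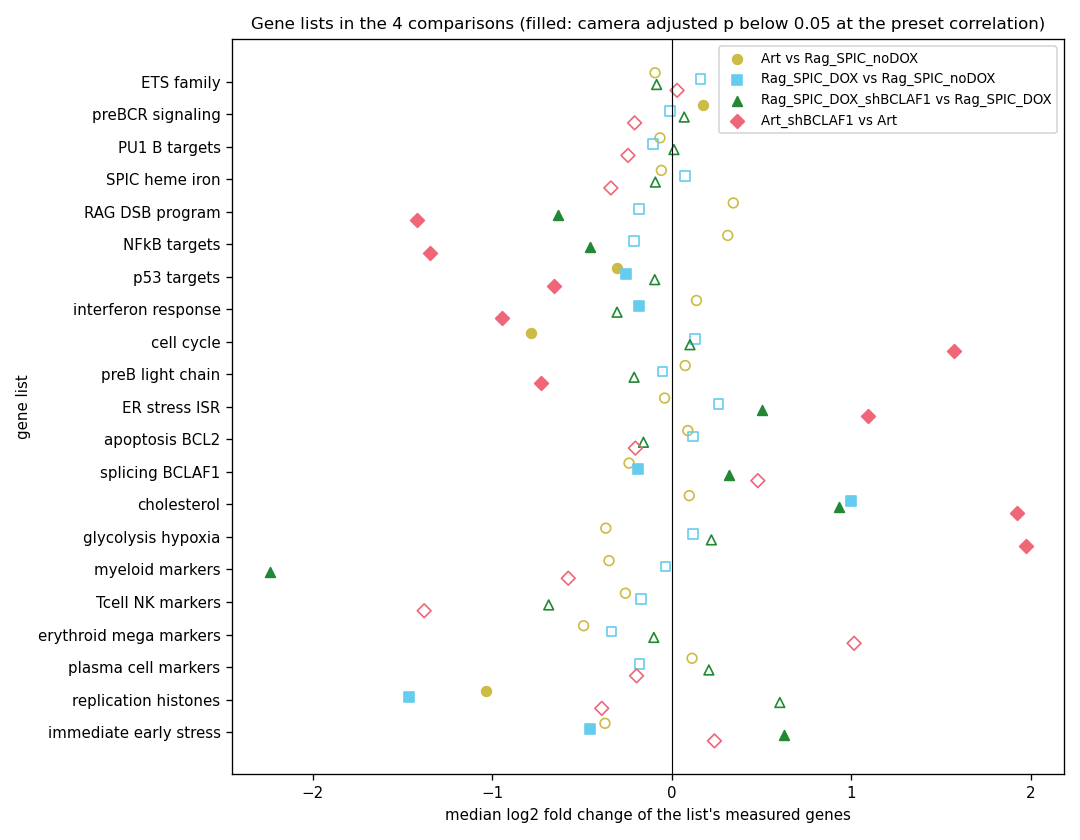
Median log2 fold change of each of the 21 gene lists in the 4 comparisons, with filled marks for a camera adjusted p below 0.05 at the preset correlation of 0.01. Of 84 tests 26 are filled, 10 up and 16 down, and 0 pass when the correlation is estimated.

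Over all 84 tests, camera at its preset correlation called 26 lists, 4, 6, 7 and 9 in the 4 comparisons in the order given. With an estimated correlation it called 0, with 10 at an unadjusted p below 0.05. The 6 libraries of a comparison give few degrees of freedom for that estimate.

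The effect of the hairpin label was then compared between the lines. In limma, 3621 genes differed between Art and Rag_SPIC_DOX cells, 1652 with the higher log2 fold change in Art and 1969 with the lower. Doxycycline, the SPIC construct and RAG breaks differ along with the line, so these differences cannot be assigned to any of them alone. Spib differed by -3.50 (adjusted p = 1.35e-06), having risen in Rag_SPIC_DOX cells and fallen in Art cells. Fam129c (1.19 and -2.71), Trio (1.31 and -2.12), Gbp4 (1.27 and -1.53), Vsir (1.30 and -1.18), Dtx3 (1.14 and -1.49) and Iqsec1 (1.13 and -1.51) did the same, with Rag_SPIC_DOX cells given before Art cells. Rag1 fell more in Art, by 1.21 log2 units (adjusted p = 0.0444). The differences of Spic (0.85, SE 0.33, adjusted p = 0.075), Bclaf1 (0.68, SE 0.41, adjusted p = 0.229) and Myc (1.72, SE 1.11, adjusted p = 0.262) did not pass.

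**Figure D3:**
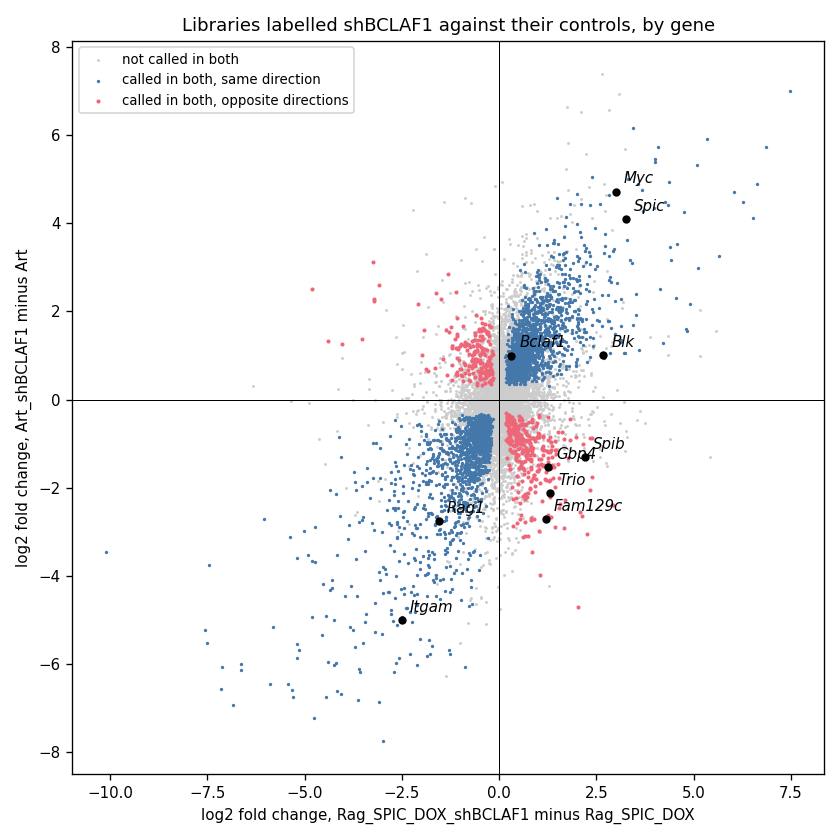
Log2 fold change of each gene for the shBCLAF1 label in Rag_SPIC_DOX cells (horizontal) and in Art cells (vertical), n = 3 libraries per group, with blue for genes changed in both in the same direction and red for opposite directions. Blue holds 2831 genes and red 489, among them Spib.

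In both lines 2831 genes changed in the same direction with the label, 1505 up and 1326 down, and 489 changed in opposite directions, where independent calls would share 1518. Myc, Bcat1 and Spic are among those that rose in both and Itgam and Ebi3 among those that fell. Art and Rag_SPIC_DOX, each against Rag_SPIC_noDOX, shared 75 genes (9 up, 66 down), with 66 in opposite directions. Independent calls would share 35.1 in the same direction, and no such number was worked out for opposite directions. The 66 in opposite directions are close to the 75, so the calls show no clear common direction. Simulations in which no gene changed shared a mean of 0, as they must where hardly any gene is called, so they are no baseline for the 75. The 75 went to 0 without any 1 Rag_SPIC_noDOX library or without Art replicate 1 or 2, to 10 and 144 without Rag_SPIC_DOX replicates 3 and 2, and to 483 without Art replicate 3. The covariance of the log2 fold changes of these comparisons across genes, which are not independent replicates, was 0.0106, against 0.0130 in 50 simulations without change that have the same control libraries in common, so the covariance is no larger than the common control gives. Arrdc3 (-1.87 and -1.92) and Dusp1 (-1.69 and -1.97) fell in both, and Tal1 (1.17 and 1.17) and Insig1 (0.72 and 1.30) rose. Of the genes that changed with doxycycline, 300 went back with the shBCLAF1 label (57 first up, 243 first down) and 488 went further. Independent calls would send 377 back, so the 300 are fewer than that. Spic itself rose further with the label, so neither count can be assigned to the label apart from the Spic level. The 300 became 4 without Rag_SPIC_noDOX replicate 1 or 3, 87 without replicate 2, 20 without Rag_SPIC_DOX replicate 3, 525 without Rag_SPIC_DOX replicate 1 and 833 without Rag_SPIC_DOX replicate 2. The Rag_SPIC_DOX libraries are in both comparisons, which alone gives a covariance of -0.0664 (r = -0.85) in simulations without change, and the measured covariance was 0.0514 (r = 0.11). Fos (-2.37, then 4.14) and Lama5 (-2.45, then 2.32) went back. Of the genes that set Art apart from Rag_SPIC_noDOX, 460 went back in Art_shBCLAF1 (265 first up, 195 first down) and 53 went further. The 460 became 0 or 1 without any 1 Rag_SPIC_noDOX library or without Art replicate 1 or 2, and 3751 without Art replicate 3. Independent calls would send 146 back. The Art libraries are in both comparisons, which alone gives reversal, with a covariance of -0.103 (r = -0.87) in simulations without change. The measured covariance was -0.36 (r = -0.49). These simulations called a mean of 0.68 such genes, but they call hardly any gene at all, so this is no baseline for the 460. How much of the 460 is reversal by the label is not known. Pcdh17 (3.55, then -4.64) and Cd86 (-2.96, then 3.41) were among them.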

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

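The tests of a label swap and of sequencing depth were chosen after the results they concern were seen, and so was the reading of the test for mixed reads. In both lines the mean of Bclaf1 and of Spic was higher in the libraries labelled shBCLAF1, by 0.32 and 3.25 in Rag_SPIC_DOX cells and by 0.99 (adjusted p = 0.0679, limma, not passing) and 4.1 in Art cells. If doxycycline and SPIC leave Bclaf1 unchanged, a swap of hairpin and control libraries among the Rag cells would put it lower in Rag_SPIC_DOX than in Rag_SPIC_noDOX. The measured difference of 0.0269 (SE 0.07) argues against a swap only under that condition, which these libraries cannot check. A swap among the Art cells was not tested. Reads from Rag_SPIC_DOX_shBCLAF1 in the Art_shBCLAF1 libraries could give the Spic reads there, since 112 genes much higher in the former than in Art reach a median of 71.8% of that level, above the 13.3% of Spic, although 3 of them lie below it, against such a mixture, and a response shared by both lines would give the same, so the test cannot tell. Art_shBCLAF1 libraries drawn from Rag_SPIC cells could do so as well. In them 18 genes that part the lines lay at a median position of 0.85 from Art at 0 to Rag_SPIC_noDOX at 1 (95% bootstrap interval 0.40 to 1.18), 5 of them below the midpoint. In Rag_SPIC_DOX_shBCLAF1 the median was 1.02, with single genes from -1.16 to 1.87, so these genes mark the lines poorly. Across all genes Art_shBCLAF1 libraries had Pearson correlations of 0.965 to 0.970 with Rag_SPIC_DOX_shBCLAF1 and 0.842 to 0.896 with Art. They had 0.899 to 0.923 with Rag_SPIC_noDOX and 0.907 to 0.952 with Rag_SPIC_DOX, so they were nearer to Rag cells without the hairpin than to Art. A response shared by both lines would give the first range but need not give this order. On the first principal component Art lay at -66.4 to -61.8, farther from Art_shBCLAF1 (58.4 to 73.0) than Rag_SPIC_noDOX did (-48.2 to -44.9). A shift along that component could give the order too, which leaves the origin open. A true effect of the hairpin on these mRNAs was not tested apart from these values.

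Myc (3.0 and 4.72) and Bcat1 (2.40 and 5.06) were higher in the libraries labelled shBCLAF1 in both lines, at 1.77 and 1.49 in Rag_SPIC_DOX cells without Rag_SPIC_DOX replicate 2. Cell-cycle genes as a list were called in Art cells and not in Rag_SPIC_DOX cells (camera adjusted p = 2.28e-11 and 0.589). With an estimated correlation the list was called in neither (camera adjusted p = 0.346 and 0.906), and its difference between the lines was not tested. A weaker effect of imatinib in these cultures may give the higher growth genes. Of 25 genes driven by ABL or the signals after it, Myc and Bcat1 not among them, 15 rose in Rag_SPIC_DOX cells, and 20 rose and 2 fell in Art cells. Their medians of 1.12 and 1.38 lay at percentile 100 of 10000 random lists in both lines. Genes driven by FOXO factors, which imatinib releases, had 1 of 26 higher and 21 lower, and 3 higher and 14 lower, with medians of -0.70 and -0.73, at percentile 0 of random lists, as a weaker effect of imatinib would have it. These lists also moved without the label, with smaller medians of -0.26 to 0.13. In Art against Rag_SPIC_noDOX both were low, at percentiles 1.38 (ABL) and 1.95 (FOXO), which a difference in imatinib effect would not give. With doxycycline they lay at 95.8 and 3.39. Random lists do not keep genes that move together, so the percentiles may overstate the evidence. Sequencing depth alone is less likely, since 4 of the 6 libraries labelled shBCLAF1 lie within the depth range of their controls, 3 of 3 in Art cells and 1 of 3 in Rag_SPIC_DOX cells, where the other 2 lie above it. A growth effect of the hairpin, or of selection for growing cells, would move the same 25 and 26 genes and stays open.

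Art replicate 3 stood apart from Art replicates 1 and 2. Across genes, which are not independent replicates, its deviation had a Spearman correlation of -0.33 with transcript length, and the difference of replicates 1 and 2 had 0.01. Degraded RNA could give such a value. The median deviation of Art replicate 3 was 0.43 in the 2310 genes with the shortest transcripts and -0.45 in the 2309 with the longest. Its correlation with GC content was 0.62, against 0.08 for replicates 1 and 2, so a bias in amplification may also have taken part. Neither correlation is particular to Art replicate 3. Art_shBCLAF1 replicate 1 deviated from its group with -0.37 for length, and Rag_SPIC_noDOX replicate 1 with 0.48 for GC content. The SD of the deviation was 0.93 in Art replicate 3, against 0.29 and 0.25 in those libraries. The lower depth of Art replicate 3 alone could not give its deviation, since thinning replicate 1 to the same depth gave an SD of 0.34 around replicate 2 against 0.95, a ratio of 0.36.

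The difference of the hairpin effect between Art and Rag_SPIC_DOX cells held 3621 genes, with 489 changed in opposite directions, and of 100 drawn splits of the lines 1, the real grouping, gave as many, the highest other giving 1745. The lines differ in level as well, so a split that mixes them widens the spread within groups. Such a split calls fewer genes whether or not the hairpin effect differs, so the highest count for the real grouping is no evidence against chance. These splits also cannot part the line from doxycycline, the SPIC construct and RAG breaks, which differ along with it. The difference was -3.50 for Spib, -1.21 for Rag1, -3.43 for Trio, -2.79 for Gbp4, -3.90 for Fam129c, -2.48 for Vsir, -2.63 for Dtx3 and -2.64 for Iqsec1. For the single comparisons the 10 splits of 3 against 3 libraries are too few for a share under 0.05. In limma the real splits called 594, 1367, 6186 and 5664 genes, in 1 of 10 splits each, and the highest other called 0, with at most 487, 873, 100 and 628 genes at an unadjusted p below 0.05. For gene lists, adjusted within that comparison, the real splits called 4, 6, 8 and 9, and the highest others 4, 7, 10 and 9, with 4, 7, 5 and 2 of 10 splits calling as many.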

How the results depend on the processing

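The fits on each comparison's own table, voom on recovered reads and the list counts without single libraries were chosen after the data were seen, the rest before. Genes changed in Art against Rag_SPIC_noDOX were 1957 with all groups in one fit, 293 in the upper 75% of genes by mean, 6547 with array weights, 314 at 1 log2 unit or more, 1033 in its own table and 701 with voom. With the replicate number as a block, limma called 0, with 1902 at an unadjusted p below 0.05. The labels do not say whether the replicate numbers mark a batch, and correlations in groups of 3 libraries cannot exclude one. Correlations of the same number were -0.23, 0.20 and -0.07 for Art with Rag_SPIC_noDOX, 0.03, 0.07 and -0.04 for Rag_SPIC_DOX with Rag_SPIC_noDOX, -0.05, -0.02 and 0.01 for Rag_SPIC_DOX_shBCLAF1 with Rag_SPIC_DOX and -0.13, 0.11 and 0.03 for Art_shBCLAF1 with Art. Samples did not all correlate best with their own number. Rag_SPIC_DOX against Rag_SPIC_noDOX gave 150 with the block, 905 in the upper 75%, 8589 with array weights, 319 at 1 log2 unit, 1839 in its own table and 1270 with voom. Rag_SPIC_DOX_shBCLAF1 against Rag_SPIC_DOX gave 10078 with array weights, 1654 at 1 log2 unit and 5171 with the block, and Art_shBCLAF1 against Art 9839, 3409 and 4779. The authors weighted libraries unequally, so that Art replicate 3 holds 0.43% of its group mean and Rag_SPIC_DOX replicate 3 94.6%. Lists called were 0 with estimated correlation and 28 with the block, and the difference between lines held 3395 genes with the block. Genes shared by Art and Rag_SPIC_DOX were 24 at 1 log2 unit, 38 in the upper 75% and 0 with the block. Genes whose SPIC response went back were 59, 193 and 53, and those whose Art difference went back 227, 236 and 0. Genes shared by the hairpin effects were 905 at 1 log2 unit and 2260 with the block. Leaving out 1 library moved Art against Rag_SPIC_noDOX between 0 (Rag_SPIC_noDOX 1 or 3, Art 1 or 2, and 1 without Rag_SPIC_noDOX 2) and 5473 (Art 3), and Rag_SPIC_DOX against Rag_SPIC_noDOX between 12 (Rag_SPIC_noDOX 1, with 15 and 401 without 3 and 2, and 58 without Rag_SPIC_DOX 3) and 4569 (Rag_SPIC_DOX 2). The range was 3945 (Rag_SPIC_DOX_shBCLAF1 2, with 4078 without 3) to 7576 for Rag_SPIC_DOX_shBCLAF1 against Rag_SPIC_DOX, 3740 (Art_shBCLAF1 1) to 9252 (Art 3) for Art_shBCLAF1 against Art, 25 to 34 for lists and 2674 to 6286 (Art 3) for the difference between lines. Overlaps ranged from 0 (any Rag_SPIC_noDOX library, Art 1 or 2, with 10 and 144 without Rag_SPIC_DOX 3 and 2) to 483 (Art 3) for Art with Rag_SPIC_DOX, 4 (Rag_SPIC_noDOX 1 or 3, with 20 without Rag_SPIC_DOX 3, 87 without Rag_SPIC_noDOX 2 and 525 without Rag_SPIC_DOX 1) to 833 (Rag_SPIC_DOX 2) for the SPIC response, 0 (Rag_SPIC_noDOX 1 or 3, Art 1 or 2, and 1 without Rag_SPIC_noDOX 2) to 3751 (Art 3) for the Art difference, and 1928 (Rag_SPIC_DOX_shBCLAF1 2) to 4188 for the hairpin effects. Among named genes the log2 fold change turned sign in 18 of 3726 refits and was labelled weaker in 565, 89 of 110 without Rag_SPIC_noDOX 1 and 88 of 110 without 3. In Art against Rag_SPIC_noDOX, Bclaf1 became 0.0347 with array weights and 0.0795 without Art 3 (-0.62 without Art 1), Spi1 -0.0570 without Art 3 (0.347 without Art 2), Dclre1c 0.351 and 0.374 with the same 2 settings (adjusted p = 0.00157 and 0.000843; -0.752 without Art 1), and Syk -0.0720 with quantile normalization. In Rag_SPIC_DOX against Rag_SPIC_noDOX, Bclaf1 became -0.0253 median centred and -0.00625 without Rag_SPIC_noDOX 1 (0.0622 without 3), Spi1 0.00215 with array weights and 0.00557 without Rag_SPIC_noDOX 2 (-0.0887 without 3), and Syk 0.0358 quantile normalized, 0.0541 with array weights, 0.000966 without Rag_SPIC_noDOX 1 and 0.147 without Rag_SPIC_DOX 1 (-0.151 without 2). In Art_shBCLAF1 against Art, Spi1 became 0.115 with array weights and 0.188 without Art 3 (adjusted p = 0.0379; -0.217 without 2), and Dclre1c 0.150 and 0.0853 without Art 1 and 2 (-0.977 without 3). The cause was not tested for any of these. No list called at the preset correlation changed its sign with scaling.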

Other observations

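The lists described here were chosen after the results were seen, and the tests on them were planned. The genes that went back with the shBCLAF1 label in Rag_SPIC_DOX cells include Rnase6 (1.32, then -2.49), Rbpj (0.62, then -0.72), a mediator of Notch signals, and Id3 (0.59, then -0.89), while Avpr2 (-2.40, then 2.18) went the other way. In Art cells Kcns1 (2.70, then -4.72), Prss12 (2.70, then -3.74) and Serpina3g (2.56, then -5.16) were higher than in Rag_SPIC_noDOX and lower with the label, and Sntb1 (-2.93, then 5.81), Tenm4 (-2.92, then 3.68), Uchl1 (-2.71, then 2.80) and P4ha2 (-2.48, then 3.68) the reverse. Fgf13 (1.41 and 1.09), Adi1 (0.96 and 0.57) and Bcl11a (0.52 and 0.56), a transcription factor of early B cells, rose in both Art and Rag_SPIC_DOX against Rag_SPIC_noDOX, and Scn3a (-2.12 and -2.04), Dnajc22 (-1.64 and -1.98) and Ryr3 (-3.36 and -1.60) fell. With the shBCLAF1 label Ly6f rose in both lines (5.33 and 5.90). Sdc2, Oaf and Grik2 also rose in both, and Psma8, Tiam1 and Zfp286 fell, from or to levels near 0 reads, so no fold is given.

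ETS-family factors were called in no comparison, with medians of -0.09, 0.16, -0.08 and 0.03 (camera adjusted p = 0.641, 0.404, 0.738 and 0.921), and in Art_shBCLAF1 against Art the median became -0.20 when libraries were centred. Etv5 (-1.32) fell and Ets1 (0.64) rose in Art against Rag_SPIC_noDOX, and Ets2 (-0.45) fell with doxycycline. Heme and iron genes had medians of -0.06, 0.07, -0.09 and -0.34 (camera adjusted p = 0.729, 0.815, 0.404 and 0.738). PU.1 and SPIB targets, at 0.01 with the label in Rag_SPIC_DOX cells, had medians of -0.07, -0.10 and -0.24 in the other comparisons (camera adjusted p = 0.922, 0.25 and 0.594), and Ciita (2.12) rose and Cybb (-1.56) fell with the label in Art cells. Apoptosis regulators had medians of 0.09, 0.12, -0.16 and -0.20 (camera adjusted p = 0.884, 0.908, 0.164 and 0.425), the value of 0.09 becoming -0.02 with quantile normalization. T-cell and NK markers had medians of -0.26, -0.17, -0.68 and -1.38 (camera adjusted p = 0.657, 0.594, 0.246 and 0.164), and erythroid markers -0.49, -0.34, -0.10 and 1.02 (camera adjusted p = 0.729, 0.633, 0.862 and 0.738). Epor (-1.44) and Itga2b (-1.29) fell with the label in Art cells. Plasma-cell markers had medians of 0.11, -0.18, 0.21 and -0.20 (camera adjusted p = 0.0861, 0.699, 0.729 and 0.657), the 0.11 becoming 0.31 without Art replicate 3, with 6 of 9 higher instead of 1 (camera unadjusted p = 0.0011).

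The median, the mean and the direction of camera differed in sign for several lists that were not called. In Art against Rag_SPIC_noDOX they were PU.1 and SPIB targets (mean 0.07), apoptosis regulators (mean -0.04) and T-cell markers (camera up). In Rag_SPIC_DOX against Rag_SPIC_noDOX they were NF-kB targets (median -0.21, mean 0.10), the RAG-break program (-0.18, 0.13), heme and iron genes and apoptosis regulators (camera down), and myeloid (-0.04, 0.44), T-cell (mean 0.11), erythroid (mean 0.19) and plasma-cell markers (mean 0.08). With the label in Rag_SPIC_DOX cells they were ETS factors (mean 0.40), cell-cycle genes (0.10, 0.21, camera down) and erythroid markers (mean 0.68), and in Art cells ETS factors (mean 0.44, camera down).

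Whether imatinib acted less on the cultures with the hairpin could be tested by measuring phosphorylated ABL targets and cell division in the same cultures, since the 25 ABL-driven genes had medians of 1.12 and 1.38. Whether the Spic reads of Art_shBCLAF1 come from the construct or from the cell's own gene could be tested with reads over the construct's junctions, as the level of 13.3% of that in Rag_SPIC_DOX_shBCLAF1 is open to both. A protein blot of BCLAF1 would tell whether the hairpin acted, since its mRNA was 0.32 log2 units higher in Rag_SPIC_DOX cells and in Art cells at 0.99 (limma adjusted p = 0.0679, not passing), or 0.54 without Art replicate 3.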
